A study of Rattus norvegicus with 18 samples.

How the data were processed

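Small RNA libraries from rat liver were compared in 3 groups of 6: lean, obese ZDF on vehicle and obese ZDF on colesevelam. Per the labels' protocols, livers were flash frozen, total RNA was isolated with a Norgen kit, and libraries were built from total RNA with an Illumina TruSeq RNA kit. A kit of that name is usually one for longer RNA, and the labels do not say how small RNA was selected. All labels give the strain of the lean rats as that of the obese ones, so the lean group is known by its name and phenotype label alone.

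The authors deposited estimated counts per mature miRNA in one table of 401 rows, with a column for each of the 18 libraries. The deposited counts are not scaled between libraries, and 297 of the 7218 values, in 42 rows are not whole, for a reason not given in the sources used here. Per the submitters' processing notes Bowtie 1.1.2 and DESeq2 1.18.1 were used. Adapter trimming, the genome build, the miRNA annotation and the counting tool are not given in the sources used here. Per the file headers, the deposited table also holds log2 fold changes from the authors' DESeq2 comparisons and their p-values, raw and adjusted. A mark of significance in the authors' deposited table stands where the unadjusted p-value is under 0.05. Dividing the rounded counts by 1 constant per library gave back the mean scaled counts of that table to rounding error for all its values but miR-184, so the authors' size factors were recovered. Put into edgeR, they gave fold changes that correlated with the deposited ones at r = 0.9999 or more across miRNAs (largest difference 0.05 on the log2 scale). No column of values per sample was left unmatched to a sample. 45 rows list more than 1 genomic location.

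Counts were rounded to whole numbers. Rows were kept by filterByExpr by group with a minimum count of 10 and a minimum total of 15, which left 112 of the 401 rows. These were scaled by TMM (factors 0.814 to 1.19) and tested with edgeR 4.0.16 in R 4.3.3, by the robust quasi-likelihood F test in one fit over all 18 libraries. P-values were BH-adjusted over all rows tested, at a threshold of 0.05. The biological coefficient of variation was 36.2%. Levels are CPM, counts scaled to one common total by TMM-scaled library totals, given as mean ± SD over 6 libraries, and fold changes are given as log2 ± SE. TMM assumes that most miRNAs do not differ, so all changes are relative to the other miRNAs of a library. Values per library (totals, shares, ratios of arms, GC slopes) were compared by two-sided exact permutation tests over all splits of 12 libraries, where the smallest possible p is 0.00216, with BH adjustment over 30 tests. Intervals of fold changes from the edgeR model and of correlations between libraries include the spread between libraries. The interval of the miR-33-5p ratio and the floors for a count of 0 cover counting error only, and reads without molecular identifiers are not independent molecules.

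The design, the lists, the alternatives and the naming rule were fixed before the data were examined. Named miRNAs were, for each comparison, the 10 largest rises and 10 largest falls past the threshold with a mean of at least 20 CPM in a group, the 6 most abundant others past the threshold, 16 miRNAs fixed by name (miR-122-5p, miR-182-5p, miR-183-5p, miR-96-5p, miR-33-5p, miR-34a-5p, miR-802-5p, miR-378a-3p, miR-192-5p, miR-194-5p, miR-29a-3p, miR-21-5p, miR-103-3p, miR-107-3p, miR-144-3p and miR-451-5p), and up to 4 members of each list described. The row for miR-182-5p carries the name miR-182. Of the fixed names miR-96-5p, miR-33-5p, miR-34a-5p and miR-144-3p had too few counts to test.

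There were 22 lists, taken from general knowledge of miRNA families, clusters, host genes and cell types: hepatocyte-enriched, SREBP-linked, FXR-linked, insulin and glucose handling, let-7, miR-200, miR-34, miR-29, miR-30, miR-17-92 and paralogous clusters, miR-23/27/24, miR-15/16/195/497, miR-221/222, miR-181, stellate cell and fibrosis-linked, leukocyte, erythroid, endothelial, muscle, pancreas and islet, Dlk1-Dio3, and PGC-1 host gene and thermogenic. Lists overlap: miR-122 and miR-194 stand in both the hepatocyte and the FXR-linked list, miR-802 in the hepatocyte and the insulin list, miR-29a in the FXR-linked, insulin and miR-29 lists, miR-29b and miR-29c in the insulin and miR-29 lists, miR-199a in the FXR-linked and the stellate list, miR-34a in the FXR-linked and miR-34 lists, and miR-144 in the FXR-linked and the erythroid list. The insulin list also shares miR-375 with the pancreas list, miR-143 with the stellate list, miR-126a with the endothelial list and miR-181b with the miR-181 list, so one change can count in several lists. Lists with 5 or more tested members were also tested with fry and with camera (limma 3.58.1, preset correlation 0.01, and an estimated correlation). fry asks whether members move one way on balance, and camera compares them with other miRNAs. No list passed camera in any comparison, with either correlation.

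Alternatives planned in advance were the size factors of DESeq2, library totals without a composition factor, upper-quartile factors, no filter, a filter of 50 CPM in 6 or more libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a replicate block, libraries that share a number in their labels summed or as a random block, the most abundant miRNA left out, and each library left out in turn. The 50 CPM filter was meant to be stricter but kept 155 rows. Alternatives added after seeing the data were the authors' size factors, correction for the GC slope of each library (as an offset and as a covariate), thinning to the smallest total of 32936 counts, the 9 libraries of low and the 9 of high GC slope apart, and the correlation without miR-6215. Assembly GRCr8 was used only for gene names, hosts and neighbours, and positions are those of the deposited table.

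The test was checked on simulated counts drawn from the real means and library sizes with known changes. In the simulation of vehicle against lean, on 118 rows, 22 of 28 changes of 2-fold and 30 of 31 of 4-fold were called, with 0 of 59 unchanged rows called. For colesevelam against vehicle, on 120 rows, 25 of 33 and 32 of 32 were called, with 2 of 55 unchanged. For colesevelam against lean, on 116 rows, 26 of 28 and 32 of 33 were called, with 1 of 55 unchanged. The simulated sets held far more changes than were called in the real data, with 52, 59 and 59 calls in all. They also drew each miRNA independently. Fewer true changes of these sizes may therefore be found in the real libraries. No libraries of a group agreed within sampling noise: the closest pair had a chi-square of 5.73 per degree of freedom, so none is a copy of another's reads. This does not show that they come from separate animals, which the labels do not state, and n counts libraries.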

Results

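Small RNA was sequenced from 18 rat liver samples in 3 groups of 6 libraries, all taken at 8 weeks of age. The groups were lean rats, obese Zucker diabetic fatty (ZDF) rats given vehicle, and obese ZDF rats given colesevelam. ZDF rats lack a working leptin receptor and become obese and diabetic. Colesevelam is a resin that binds bile acids in the gut, so that the liver makes more of them from cholesterol. The question stated for the study was which liver microRNAs (miRNAs) differ between vehicle and colesevelam, and the lean group allowed the obese rats of each kind to be compared with lean rats. Nothing in the labels says that each library came from a separate animal, so p-values measure the spread between these libraries, which may be technical in part.

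The libraries held between 32936 and 881452 miRNA counts. Lean libraries held 328767 ± 297623 counts (mean ± SD, n = 6), vehicle libraries 66504 ± 41460 and colesevelam libraries 66280 ± 33701. On the log2 scale the vehicle libraries lay below the lean ones by 4.21-fold (difference −2.07, exact two-sided permutation p = 0.00433, adjusted p = 0.0216 over 30 such tests). Colesevelam libraries lay 4.14-fold below lean ones (difference −2.05, exact permutation p = 0.00433, adjusted p = 0.0216), and the 2 obese groups differed by 0.02 (exact permutation p = 0.948). Of the miRNAs in the table, 112 had enough counts to be tested, and these held 99.5% of all counts. A count of 0 allowed up to 3.40 CPM (counts scaled to one common library total) in the deepest library and up to 91.1 CPM in the shallowest, for counting error only. The liver miRNA miR-192-5p was the most abundant, with 23.1% of the counts, followed by miR-22-3p with 9.41%, miR-378a-3p with 6.32% and miR-21-5p with 5.91%; miR-122-5p, the classic hepatocyte miRNA, ranked 7 with 4.49%. The share of miR-192-5p was 26.0 ± 6.68% in lean, 20 ± 5.04% in vehicle and 23.3 ± 5.70% in colesevelam libraries (n = 6 each), and no pair of groups differed by the exact permutation test (smallest p = 0.108). Within groups, 41% of the variance between libraries lay on one axis that followed the GC content of the miRNAs. The slope of level on GC content did not differ past the threshold between groups (exact permutation p = 0.242 for vehicle against lean, 0.258 for colesevelam against vehicle and 0.922 for colesevelam against lean).

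**Figure D1:**
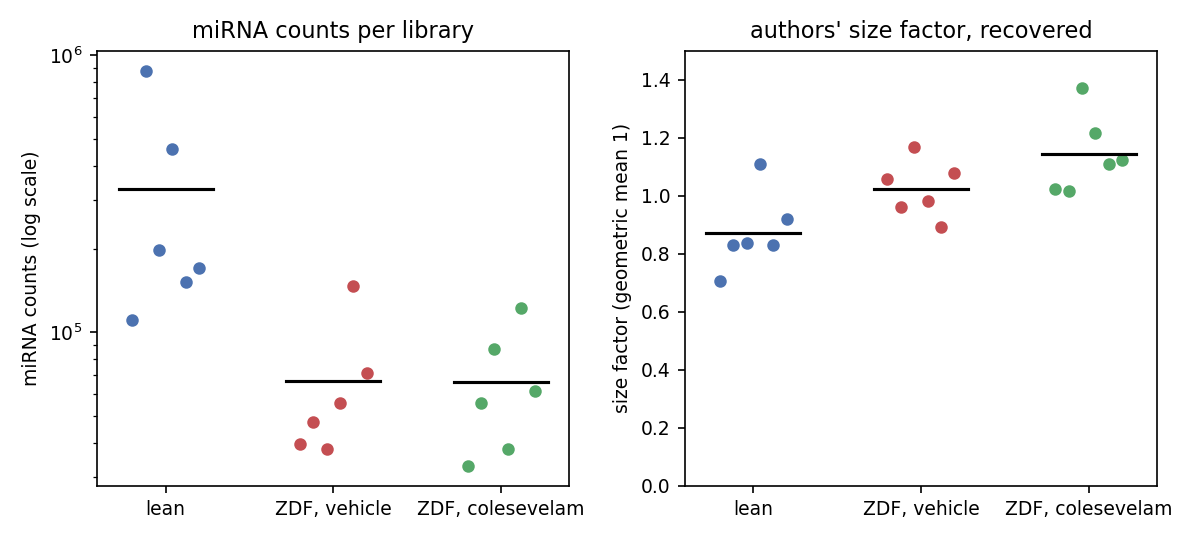
Total miRNA counts per library on a log axis, and the size factor of each library recovered from the authors' deposited table; points are libraries and lines are group means. Lean libraries held 110352 to 881452 counts and vehicle libraries 37910 to 147313, while the size factors of all 18 libraries lay between 0.706 and 1.37.

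Vehicle against lean asked what differs in the obese liver. Relative to the other miRNAs of a library, 4 miRNAs were higher and 3 lower in vehicle than in lean libraries. miR-21-3p, the minor arm of the injury- and fibrosis-linked miR-21 precursor, rose 6.63-fold, from 89.3 ± 30.2 to 598 ± 146 CPM (mean ± SD, n = 6), and every vehicle library lay above every lean library. miR-378a-3p, whose gene lies within the gene of the mitochondrial coactivator PGC-1β, rose 1.74-fold from 42780 ± 3676 to 74258 ± 21522 CPM, again without overlap, and miR-140-3p rose 2.28-fold from 608 ± 106 to 1397 ± 539 CPM. miR-200b-3p, a miRNA of epithelia including bile duct cells, fell 3.84-fold from 306 ± 102 to 79.2 ± 39.8 CPM. miR-182, a member of the cluster of miR-183, miR-96 and miR-182 that is linked to sterol regulation through the transcription factor SREBP-2, fell 1.85-fold from 4582 ± 1020 to 2486 ± 594 CPM. miR-142-5p, a leukocyte miRNA, fell 2.42-fold from 1493 ± 853 to 611 ± 256 CPM.

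In edgeR's quasi-likelihood test with Benjamini-Hochberg (BH) adjustment the log2 fold change (± SE) was 2.73 ± 0.32 for miR-21-3p (adjusted p = 2.12e-06), −1.94 ± 0.35 for miR-200b-3p (adjusted p = 0.000653) and −0.88 ± 0.19 for miR-182 (adjusted p = 0.00362). It was 1.19 ± 0.29 for miR-140-3p (edgeR adjusted p = 0.01004), 0.80 ± 0.21 for miR-378a-3p (0.0199) and −1.27 ± 0.36 for miR-142-5p (0.0328). miR-6215 was the seventh miRNA called, at 7.92 ± 1.76 (edgeR adjusted p = 0.01004). It was uneven: 5 of the 6 vehicle libraries held 784 to 7009 CPM, while the remaining vehicle library and all lean libraries stayed at or below 60.6 CPM. The log2 fold change was 8.78 without lean 1 and 7.32 without vehicle 3. Unadjusted, 21 miRNAs had p under 0.05. Among the 112 tested miRNAs the libraries of the groups did not overlap in 3, against 0.216% of miRNAs by chance: miR-21-3p, miR-378a-3p and miR-532-5p, the last not called (edgeR adjusted p = 0.119) and named here after its values were seen.

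The miRNA lists fixed in advance described few further differences between vehicle and lean. In the SREBP-linked list 1 of 2 tested members fell, or 2 when adjusted over the list alone. The other was miR-183-5p, at a log2 fold change of −0.80 ± 0.30 (edgeR adjusted p = 0.119 over all miRNAs), while miR-96-5p and miR-33-5p, with 16 and 31 counts over all lean libraries, were too low to test. In the stellate cell and fibrosis-linked list 1 of 5 members, miR-21-3p, rose, and the others lay near 0, with miR-21-5p at 0.19 ± 0.24, miR-143-3p at 0.09, miR-199a-3p at −0.06 and miR-145-5p at −0.05. That list moved up on balance by fry (BH-adjusted p = 0.00181, and 0.0419 for change in either direction), but not against other miRNAs by camera (adjusted p = 0.136, and adjusted p = 0.214 with an estimated correlation). Of the 5 tested members of the PGC-1 host gene and thermogenic list miR-378a-3p alone rose over all miRNAs, and 2 did when adjusted over the list alone, with miR-378b at 0.73 ± 0.26 (edgeR adjusted p = 0.110). Reads of miR-378b can be shared with miR-378a-3p, since the sequences are closely related. The miR-200 family had 1 tested member, miR-200b-3p, which fell. In the leukocyte list 1 of 4 members fell and none rose, over all miRNAs and over the list alone; miR-146a-5p was at 0.03, miR-146b-5p at 0.01 and miR-150-5p at −0.00. In the list of miR-23/27/24 clusters none of 5 members passed over all miRNAs, and miR-23b-3p (0.59 ± 0.21) did when adjusted over the list alone. miR-375-3p, the only tested member of the pancreas, islet and neuronal list, was at −1.07 ± 0.37 (edgeR adjusted p = 0.110) and passed over the list alone.

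Hepatocyte miRNAs were not called. None of the 9 tested members of the hepatocyte-enriched list passed, with miR-122-5p at −0.24 ± 0.32, miR-192-5p at −0.46 ± 0.26, miR-148a-3p at −0.45 ± 0.29 and miR-802-5p at −0.07 ± 0.31. The summed share of that list was 38.0% of counts in lean and 29.8% in vehicle libraries (exact permutation p = 0.0368, adjusted p = 0.138). No member passed, over all miRNAs or over the list alone, among the 5 tested of the bile acid receptor (FXR)-linked list, the 12 of the insulin and glucose handling list, the 10 of the let-7 family, the 2 of the miR-29 family, the 7 of the miR-30 family, the 4 of the miR-17-92 clusters, the 5 of the group of miR-15, miR-16, miR-195 and miR-497, the 3 of the miR-181 family, the 2 endothelial rows and the single erythroid one. Of these miR-29a-3p was at 0.27 ± 0.17, miR-103-3p at 0.40 ± 0.20, miR-107-3p at 0.25 ± 0.23, miR-194-5p at −0.01 ± 0.19 and miR-451-5p at −0.59 ± 0.41. The median and the mean differed in sign in the insulin and glucose handling (0.05 and −0.02), let-7 (0.03 and −0.02), miR-17-92 (0.15 and −0.02) and leukocyte lists (0.01 and −0.31). The miR-34 family, miR-221 and miR-222, the muscle list and the Dlk1-Dio3 imprinted cluster had no tested member in any comparison.

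With the authors' size factors, which do not follow the miRNA total, 110 of the 112 miRNAs were called against lean and 1 of them was higher, the median log2 fold change was −2.38, miR-140-3p and miR-378a-3p turned to −1.27 and −1.64, and miR-21-3p, at 0.34, lost its call. miR-142-5p lost its call in 8 of the 12 fits that left out a library, namely lean 2, 4 and 6 or vehicle 1, 2, 3, 4 and 6 (edgeR adjusted p = 0.0516 to 0.148), and miR-378a-3p lost its call without lean 1 or 4 or vehicle 3 or 6 (edgeR adjusted p = 0.0546 to 0.0679). With libraries of one label number summed, miR-140-3p (edgeR adjusted p = 0.0666) and miR-6215 (0.0643) lost their calls, and miR-378a-3p did with upper-quartile factors (0.0546) and a replicate block (0.0640). miR-142-5p also lost its call with limma-voom, with miR-192-5p left out and in a fit of only these groups, where miR-6215 was not tested.

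Colesevelam against vehicle asked what the resin changed in obese rats. The largest rises were in the cluster of miR-183, miR-96 and miR-182: miR-183-5p rose 5.95-fold, from 55.2 ± 13.2 to 332 ± 69.2 CPM (mean ± SD, n = 6), and miR-182 rose 5.15-fold, from 2486 ± 594 to 12792 ± 1318 CPM. In both, every colesevelam library lay above every vehicle library. The inflammation-linked pair miR-146a-5p and miR-146b-5p rose 2.17-fold and 2.41-fold, miR-99a-5p and miR-99b-5p rose 2.03-fold and 1.99-fold, and the abundant miR-10a-5p and miR-191a-5p rose 1.71-fold and 1.70-fold. miR-150-5p, a miRNA of mature lymphocytes, fell 2.42-fold from 725 ± 319 to 305 ± 99.4 CPM, and miR-28-5p, miR-148a-5p and miR-30d-5p fell 1.83-fold, 1.58-fold and 1.51-fold.

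The log2 fold change was 2.36 ± 0.19 for miR-182 (edgeR adjusted p = 3.01e-09) and 2.57 ± 0.29 for miR-183-5p (6.84e-07). In the deposited table both lie on the minus strand of chromosome 4, at positions 57221577 to 57221601 for miR-182 and 57225432 to 57225453 for miR-183-5p, in a rat genome build not given in the sources used here. In the GRCr8 assembly the genes of miR-182, miR-96 and miR-183 neighbour each other. The miRNA between them, miR-96-5p, was not detectable as different at this depth, with 2 counts over all libraries of each obese group. The other rises were 1.27 ± 0.29 for miR-146b-5p (edgeR adjusted p = 0.00880), 1.12 ± 0.27 for miR-146a-5p (0.0114), 1.02 ± 0.25 for miR-99a-5p (0.0114), 0.99 ± 0.30 for miR-99b-5p (0.0340), 0.77 ± 0.20 for miR-10a-5p (0.0154) and 0.76 ± 0.19 for miR-191a-5p (0.0134). The pairs miR-146a and miR-146b, and miR-10a and miR-10b, are near-identical in sequence, so reads can be shared within a pair. The sequences of miR-99a-5p and miR-99b-5p are related but differ at several positions. The falls were −1.27 ± 0.38 for miR-150-5p, −0.87 ± 0.26 for miR-28-5p and −0.59 ± 0.18 for miR-30d-5p (edgeR adjusted p = 0.0340 each) and −0.66 ± 0.21 for miR-148a-5p (0.0411). In all, 12 miRNAs changed, 8 up and 4 down, 24 had an unadjusted p under 0.05, and among the 112 tested miRNAs the groups did not overlap in 6, all of them called, against 0.216% of miRNAs by chance.

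**Figure D2:**
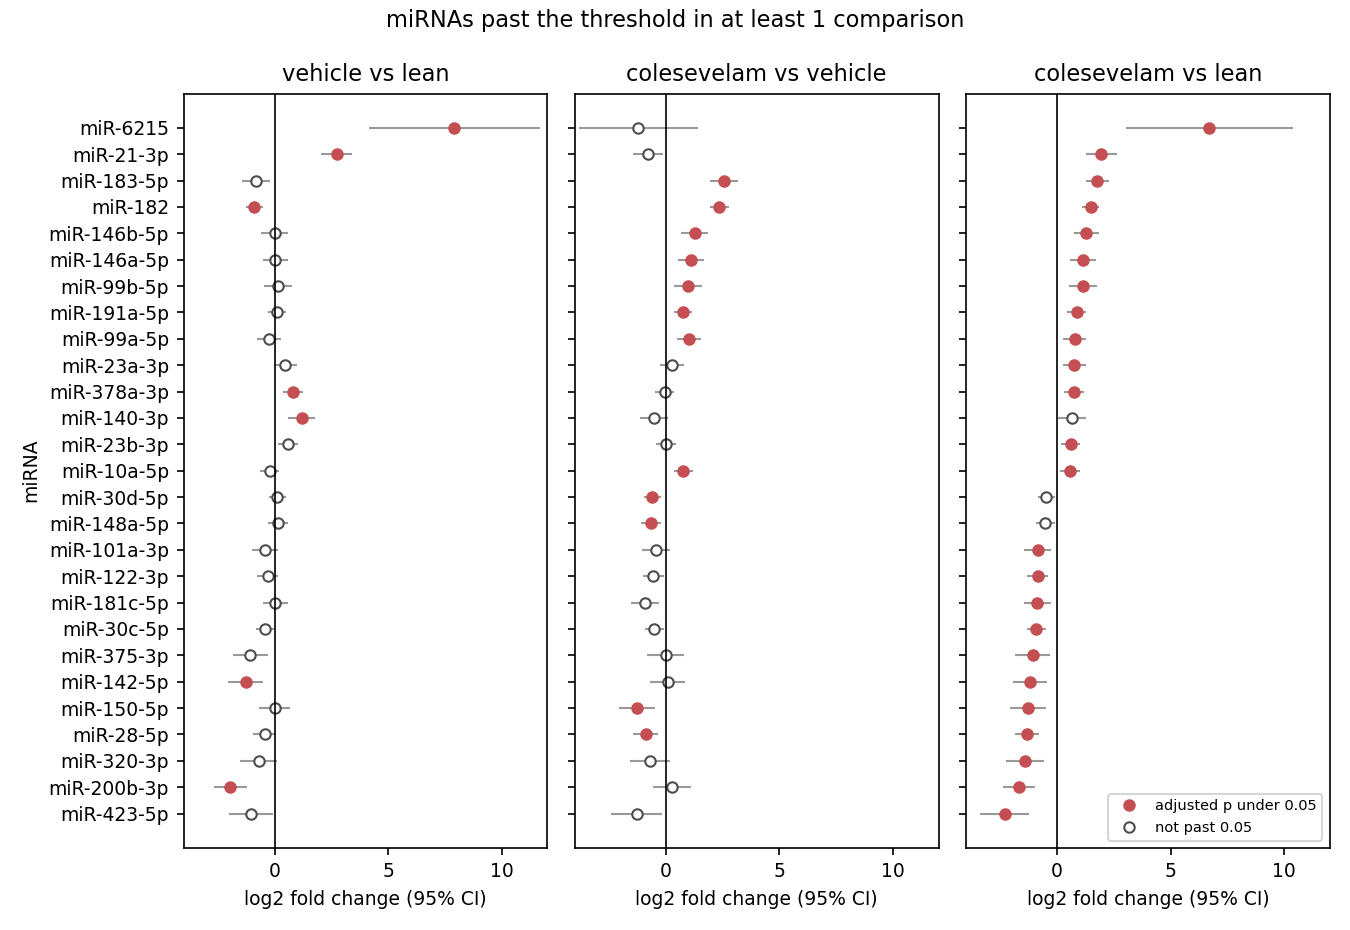
The log2 fold change of 27 miRNAs called in at least 1 comparison, with 95% confidence intervals from the edgeR model, in a panel for each comparison; 6 libraries per group, changes relative to the other miRNAs of a library. miR-182 lay at −0.88 in vehicle against lean, 2.36 in colesevelam against vehicle and 1.48 in colesevelam against lean; with the authors' size factors the last turned to −1.38.

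By list, both tested members of the SREBP-linked list rose with colesevelam, over all miRNAs and over the list alone. miR-33-5p, whose gene lies in the SREBP-2 gene Srebf2 in GRCr8, had 3 counts over the vehicle and 2 over the colesevelam libraries and was not tested. In the leukocyte list 2 of 4 members rose (miR-146a-5p and miR-146b-5p) and miR-150-5p fell, with the same counts over the list alone, while miR-142-5p was at 0.09 ± 0.37. In the hepatocyte-enriched list 1 of 9 fell, miR-148a-5p, the minor arm of its precursor, also over the list alone; miR-148a-3p was at 0.15 ± 0.29, miR-122-5p at 0.35 ± 0.32 and miR-192-5p at 0.36 ± 0.26. In the miR-30 family 1 of 7 fell, miR-30d-5p, also over the list alone, and the family moved down on balance by fry (BH-adjusted p = 0.0208) but not by camera (adjusted p = 0.553, and adjusted p = 0.627 with an estimated correlation). No member of the stellate cell and fibrosis-linked list passed, with miR-21-3p at −0.78 ± 0.31 (edgeR adjusted p = 0.136) and miR-199a-3p at −0.65 ± 0.29. That list moved down on balance by fry (BH-adjusted p = 0.0208) and not by camera (adjusted p = 0.553, and adjusted p = 0.627 with an estimated correlation). None of the 3 tested members of the miR-181 family passed over all miRNAs, and miR-181c-5p (−0.91 ± 0.30, edgeR adjusted p = 0.0523) did over the list alone.

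No member of the FXR-linked list, named for the bile acid receptor, passed: miR-122-5p aside, miR-29a-3p was at −0.02 ± 0.17, miR-194-5p at −0.01 ± 0.19 and miR-122-3p at −0.55 ± 0.22. For the insulin and glucose handling list miR-103-3p was at 0.13 ± 0.21, miR-107-3p at −0.19 ± 0.24, miR-802-5p at −0.13 ± 0.32 and miR-375-3p at −0.00, and none of the 12 passed. The let-7, miR-200, miR-29, miR-17-92, miR-23/27/24, miR-15 and miR-16, erythroid, endothelial, pancreas and PGC-1 host gene lists had no member past the threshold either, over all miRNAs or over the list alone; miR-200b-3p was at 0.26 ± 0.40, miR-451-5p at −0.04 ± 0.46 and miR-378a-3p at −0.05 ± 0.21.

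miR-148a-5p kept its call only without vehicle 1, miR-30d-5p only without vehicle 5, miR-150-5p only without colesevelam 1 or vehicle 4 or 5, and miR-28-5p only without colesevelam 1 or 2 or vehicle 1, 4 or 5, while miR-99b-5p lost its call without vehicle 5 (edgeR adjusted p = 0.0832), miR-10a-5p without vehicle 6 (0.0550), and 7 calls remained in all without vehicle 6. All 4 falls also missed the threshold with libraries of one label number summed, with a replicate block and with a filter of 50 CPM, where 7, 7 and 8 of the 8 rises were called. Without a filter 5 of the 8 rises and 1 of the 4 falls were called. miR-99a-5p and miR-191a-5p kept their calls whichever library was left out, but missed the threshold in at least 1 other planned fit. Scaling also changed the split: 7 of 14 calls were rises with library totals only, 6 of 6 with upper-quartile factors and 2 of 2, miR-182 and miR-183-5p, with the authors' size factors, where the median was −0.36.

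Colesevelam against lean asked what set treated obese rats apart from lean rats. With 24 miRNAs, 13 up and 11 down, it gave the most calls of the 3 comparisons. miR-21-3p remained above lean in the treated rats, 3.87-fold at 355 ± 156 CPM (mean ± SD, n = 6), and miR-378a-3p 1.67-fold at 71630 ± 19461 CPM. miR-182 and miR-183-5p were 2.79-fold and 3.42-fold above lean, and miR-146a-5p, miR-146b-5p, miR-99b-5p, miR-191a-5p, miR-99a-5p and miR-10a-5p were higher as well. miR-423-5p was 4.95-fold lower than in lean libraries (137 ± 93.6 against 633 ± 416 CPM), miR-200b-3p 3.21-fold, miR-320-3p 2.64-fold and miR-28-5p 2.46-fold lower, and the minor arm of the hepatocyte miR-122 precursor, miR-122-3p, was 1.80-fold lower. The colesevelam level of miR-200b-3p, 99.9 CPM, was not far above the 55.3 CPM that a count of 0 allowed on average there, so the size of its fall is uncertain.

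The log2 fold change was 1.77 ± 0.24 for miR-183-5p (edgeR adjusted p = 1.44e-05), 1.48 ± 0.19 for miR-182 (7.29e-06), 1.95 ± 0.32 for miR-21-3p (0.000168) and 6.70 ± 1.73 for the uneven miR-6215 (0.0121). The last rests mainly on colesevelam 1, at 6096 CPM; colesevelam 3 held 977 CPM and the other 4 at most 80.3, and the log2 fold change was 4.61 without colesevelam 1 (edgeR adjusted p = 0.0269) and 7.57 without lean 1. Further rises ranged from 0.57 for miR-10a-5p to 1.28 for miR-146b-5p, with miR-23a-3p at 0.76 ± 0.25 and miR-23b-3p at 0.60 ± 0.21. Falls were −2.31 ± 0.52 for miR-423-5p (edgeR adjusted p = 0.00265), −1.68 ± 0.34 for miR-200b-3p (0.00137), −1.30 ± 0.26 for miR-28-5p (0.00117), −0.91 ± 0.20 for miR-30c-5p (0.00200) and −0.85 ± 0.22 for miR-122-3p (0.00883). The remaining falls were −1.40 for miR-320-3p, −1.27 for miR-150-5p, −1.18 for miR-142-5p, −1.07 for miR-375-3p, −0.87 for miR-181c-5p and −0.85 for miR-101a-3p. Unadjusted, 44 miRNAs had p under 0.05, and among the 112 tested miRNAs the groups did not overlap in 9, all of them called (0.216% of miRNAs by chance).

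**Figure D3:**
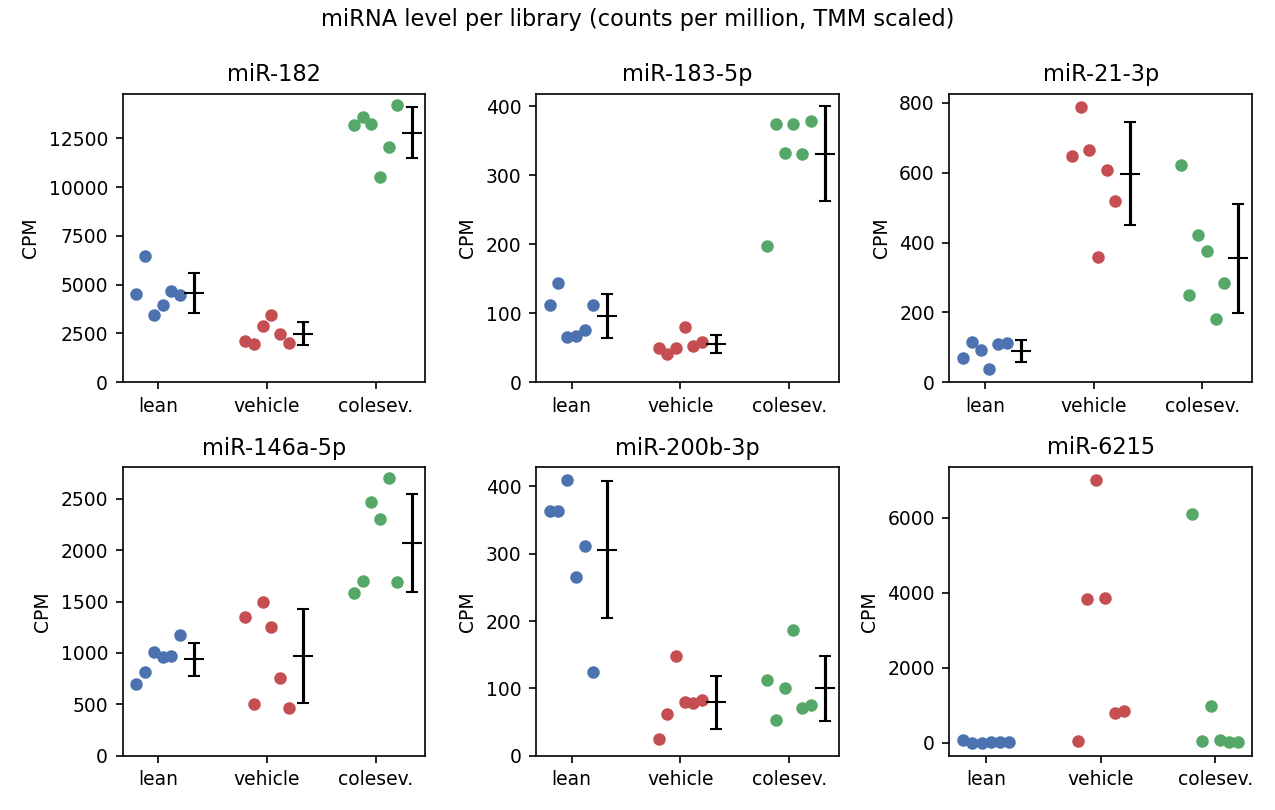
Level of 6 miRNAs in each library, in CPM after TMM scaling; points are libraries (6 per group), and bars give mean ± SD except for miR-6215, where the libraries fall apart into high and low values. miR-182 lay at 4582 ± 1020 CPM in lean, 2486 ± 594 in vehicle and 12792 ± 1318 in colesevelam libraries.

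In the leukocyte list 2 of 4 members rose and 2 fell (miR-142-5p and miR-150-5p), with the same counts over the list alone. In the hepatocyte-enriched list 2 of 9 fell, miR-122-3p and miR-101a-3p, and 2 also over the list alone, while miR-122-5p was at 0.12 ± 0.32 and miR-192-5p at −0.10 ± 0.26. Of the FXR-linked list 1 of 5 fell, miR-122-3p, and 2 over the list alone, with miR-199a-3p at −0.72 ± 0.28 (edgeR adjusted p = 0.0668), miR-29a-3p at 0.25 ± 0.17 and miR-194-5p at −0.02 ± 0.19. In the miR-30 family 1 of 7 fell, miR-30c-5p, also over the list alone, and the family moved down on balance by fry (BH-adjusted p = 0.0117) but not by camera (adjusted p = 0.352, and adjusted p = 0.764 with an estimated correlation). In the miR-23/27/24 clusters 2 of 5 rose, miR-23a-3p and miR-23b-3p, and over the list alone 3 rose and 2 fell, with miR-24-3p at 0.65 and miR-27a-3p at −0.66 and miR-27b-3p at −0.43. Both members of the SREBP-linked list rose, miR-21-3p alone rose in the stellate and fibrosis-linked list (1 up and 1 down, miR-199a-3p, over the list alone), and miR-378a-3p alone in the PGC-1 host gene list, in each case with the same count of rises over the list alone. One member fell in each of the miR-200 family (miR-200b-3p), the miR-181 family (miR-181c-5p) and the pancreas list (miR-375-3p), over all miRNAs and over the list alone. Of the insulin and glucose handling list 1 of 12 fell, miR-375-3p, and none over the list alone; miR-103-3p was at 0.53 ± 0.20 (edgeR adjusted p = 0.0634), miR-107-3p at 0.06 ± 0.23 and miR-802-5p at −0.20 ± 0.31. That list's direction was down by camera and up by fry, past the threshold in neither. The miR-17-92 clusters had no call over all miRNAs and 1 fall over the list alone, miR-19b-3p at −1.32 ± 0.48. The let-7 and miR-29 families, the group of miR-15, miR-16, miR-195 and miR-497 and the erythroid and endothelial lists had none in either count; miR-21-5p was at 0.00 ± 0.24 and miR-451-5p at −0.63 ± 0.42.

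With the authors' size factors 109 miRNAs were called against lean, 1 of them higher, at a median of −2.76, and 12 of the 13 rises turned to falls, miR-6215 excepted; with library totals only 11 of 29 calls were rises. Leaving out a library ended 9 of the 24 calls in at least 1 fit: miR-10a-5p (10 of 12 fits), miR-375-3p (9), miR-101a-3p (7), miR-23a-3p (6), miR-142-5p and miR-23b-3p (5 each), miR-181c-5p (4), miR-99a-5p (without colesevelam 4 or lean 1 or 5) and miR-320-3p (without lean 5, edgeR adjusted p = 0.0521). miR-150-5p was kept in those fits but missed the threshold in another planned one. With libraries of one label number summed 16 of the 24 calls were kept, and with a replicate block 19.

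Whether colesevelam moved miRNAs opposite to the obese-lean difference was asked across all 112 miRNAs. miR-182 was the one miRNA called in opposite directions, down in vehicle against lean and up with colesevelam (1 found, 0.214 expected from independent lists, which these are not), and no miRNA went up and then down (0.143 expected). Simulated sets of unchanged groups with the vehicle libraries shared, 100 in number, gave 0 opposite calls. That was nearly fixed in advance, since each set held at most 1 called miRNA (mean 0.07). These sets also drew each miRNA independently, without the GC axis of the real libraries. With the real vehicle libraries split between the comparisons there were 0 to 1 opposite calls (mean 0.6). The 4 called rises of vehicle over lean, miR-6215, miR-21-3p, miR-378a-3p and miR-140-3p, were at −1.22 ± 1.23, −0.78 ± 0.31, −0.05 ± 0.21 and −0.53 ± 0.29 with colesevelam, none past the threshold. The log2 fold changes correlated at r = −0.28 across miRNAs, which are not independent replicates, with a covariance of −0.155. Both comparisons share the vehicle libraries: 100 simulated sets of unchanged groups gave a mean r of −0.50 (range −0.73 to −0.13) and a mean covariance of −0.063 (range −0.126 to −0.016). With the vehicle libraries split between the comparisons the mean was r = −0.17 (range −0.40 to 0.15), with a mean covariance of −0.094 (range −0.206 to 0.105). The covariance without miR-6215 was −0.070.

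In the authors' deposited table of comparisons 183 miRNAs had a value for vehicle against lean, and 178 had an adjusted p under 0.05, 1 of them higher and 177 lower, at a median log2 fold change of −2.41. The authors' deposited table gave 178 miRNAs for colesevelam against lean, all lower, at a median of −2.87. For colesevelam against vehicle the authors' deposited table marked 29 of 127 miRNAs by an unadjusted p under 0.05, of which 4 were higher and 25 lower, and 8 passed after adjustment, 2 higher and 6 lower. miR-182 stood at 2.00 (adjusted p = 0.000538) and miR-183-5p at 2.25 (adjusted p = 0.00116) in the authors' deposited table for that comparison.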

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

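Of the tests in this part, the planned ones are the search for libraries far from their group and the counts over other splits of the libraries. For the GC test of miR-6215 the bound was written before its outcome, but the pattern and the GC slope sets came from these data. The other tests were chosen only after the result was seen.

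A single library far from the other 5 of its group was found in 10 of 141 groups of levels, where chance alone gives 7.05. The value given is the gap to the nearest library over the range of the group, listed where it passed the tabulated 1 in 20 value. Lean 6 was low for miR-200b-3p (0.629), miR-103-3p (0.685), miR-150-5p (0.767) and miR-375-3p (0.805), and lean 1 for miR-146b-5p (0.6254). Colesevelam 1 was low for miR-183-5p (0.790), colesevelam 6 for miR-802-5p (0.680) and miR-181c-5p (0.708), and colesevelam 3 for miR-150-5p (0.702) and miR-23b-3p (0.675). For miR-184 the mean of scaled counts in the authors' deposited table for colesevelam against vehicle was 132 times the mean from its own counts, while the other 126 miRNAs had a ratio of 1.

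The bound set in advance against chance was that under 5 of 100 splits of the libraries give as many changed miRNAs. All 3 counts met it, with each library taken as separate. For vehicle against lean this does not exclude chance, since another split gave far more calls than the real one. For colesevelam against vehicle 1 of 100 splits of the 12 libraries, the real one, gave as many as 12, and the highest other gave 3. For colesevelam against lean it was again 1 of 100, with 24 against 2. For vehicle against lean 3 of 100 splits gave as many as the real 7, and the highest other gave 46. That split points to a structure of the samples: it set 0 of 6 against 5 of 6 libraries with a low GC slope. Within the 9 libraries of low GC slope (2 vehicle and 3 lean among them) vehicle against lean gave 0 calls (edgeR quasi-likelihood, 9 at an unadjusted p under 0.05, other tools not run there). Within the 9 of high slope (4 vehicle and 3 lean among them) it gave 11. All 7 called miRNAs kept their direction in both, which is weak support, as they were called on these same libraries.

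With the authors' size factors nearly all miRNAs lay below lean in both obese groups. With those factors the median log2 fold change of vehicle against lean was −2.48, −2.32 and −2.25 in miRNAs of low, middle and high GC content, so no GC range was spared. With nearly all miRNAs lower that outcome could hardly differ, so the test cannot decide on a partial loss by GC content. That test replaced a bound on the rank correlation with GC content, which at 0.267 lay too near the bound to decide. Within groups the authors' factors correlated with the miRNA totals at r = 0.172 (95% interval −0.354 to 0.615), against 0.989 for the factors of DESeq2 from the miRNA counts, so the shift may lie in factors that follow something other than the miRNA total. Whether the liver of obese rats held fewer miRNA molecules cannot be told apart from a lower recovery of miRNA or another library batch, because no spike-in is in the table; miRNA counts per authors' factor were lower by −2.31 in vehicle than in lean libraries.

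miR-182 and miR-183-5p were higher with colesevelam than with vehicle, the clearest change of the series. The vehicle level of miR-183-5p was near what a count of 0 allowed, so the size of its rise is uncertain. With the GC slope removed the log2 fold changes were 2.38 ± 0.19 and 2.48 ± 0.29. That correction could move them little, so its outcome was nearly fixed in advance. Their GC content, 48% and 40.9%, lies far from the extremes of 27.3% and 72.7%, and the mean slope differed by only −0.173 log2 per 10 points. A linear GC slope of this size is too small to give the rise, and other forms of GC bias were not tested. More bile duct or other epithelial RNA is argued against by a difference of 2.32 ± 0.33 for miR-182 and 2.53 ± 0.40 for miR-183-5p from the summed miR-200 family of 8 miRNAs (0.05 ± 0.27, from 83 vehicle and 72 colesevelam counts). A candidate explanation is a response of the SREBP-2 pathway to bile acid loss. It stays open: miR-33-5p, hosted by Srebf2, had a ratio of 0.669 (95% interval 0.0559 to 5.84), from too few counts to decide.

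miR-6215 was high in 7 of the 12 obese libraries (784 to 7009 CPM) and at most 80.3 CPM in all others. GC bias is argued against, as 4 of the high libraries had a low and 3 a high GC slope, with low obese libraries on both sides. As for RNA of another tissue that brings further miRNAs, 0 of the 111 other tested miRNAs followed it at a rank correlation of 0.8 or more (highest 0.643). This argues only against a source that brings tested miRNAs along in step. It cannot decide on a source whose other miRNAs lie among the 289 rows not tested. A batch marked by the label numbers is argued against by 1 of 3 pairs of obese libraries with one number that fell on different sides of 100 CPM. Obesity itself stays open, and so does a read source specific to this one sequence, which was not tested.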

How the results depend on the processing

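The tests with the authors' size factors, GC slope, thinned libraries, libraries apart by GC slope and without miR-6215 were chosen only after the result was seen; the other tests were planned.

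Changed miRNAs numbered 7, 12 and 24 (vehicle against lean, colesevelam against vehicle, colesevelam against lean), 8, 14 and 33 with DESeq2, and 6, 10 and 23 with limma-voom. Leaving out 1 library gave 5 to 8, 7 to 12 and 17 to 32. For vehicle against lean the count moved to 110 with the authors' size factors, 16 with the GC slope as a covariate, and 0 and 11 in the 9 libraries of low and the 9 of high GC slope. For colesevelam against vehicle it moved to 6 with upper-quartile factors, 7 without a filter, 7 with libraries of one label number summed, 7 without vehicle 6, 2 with the authors' size factors, 24 with the GC covariate and 5 in the libraries of low GC slope. For colesevelam against lean it moved to 39 with the label number as a random block, 109 with the authors' size factors and 43 with the GC covariate. The libraries of low or high GC slope are fewer samples. With the random block the correlation within label numbers was estimated at −0.216, and a negative value narrows the SE of a group mean, which can raise the count. The cause of the other moves was not tested, save that the authors' factors shift the median of all miRNAs to −2.38, −0.36 and −2.76. Among the other scalings and filters, over the same miRNAs, it moved by over 0.1 for colesevelam against vehicle with library totals (by −0.11), miR-192-5p left out (−0.11) and the 50 CPM filter (0.14), and for colesevelam against lean with upper-quartile factors (0.10), miR-192-5p left out (−0.14) and the 50 CPM filter (0.15). Relative to the shift with the authors' factors miR-21-3p stayed at 2.72 in vehicle against lean and miR-182 at 2.36 in colesevelam against vehicle. All 7, 12 and 24 calls were kept with the GC slope removed or as a covariate. They kept their direction in both sets of libraries by GC slope, which is weak support, as they were called on these same libraries. Of them 0, 4 and 15 passed the threshold in the libraries of low GC slope, and 5, 8 and 15 in those of high slope.

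With a replicate block 6, 7 and 20 miRNAs were called. The residuals gave no sign that sample numbers pair the libraries, though a weak pairing could be hidden by the GC axis. Residuals of same-numbered samples correlated at −0.59 to 0.56 (mean −0.09, against 0.02 for other numbers), and 0 libraries lay closest to their own number. Libraries of one group with the same label number did not resemble each other either (mean residual correlation −0.37, against −0.17 for other pairs within groups). If those numbers mark animals, the groups hold 4 lean, 5 vehicle and 4 colesevelam animals. With such libraries summed 5, 7 and 17 miRNAs were called, 16 of the 17 among the 24. The 39 of the random block, fitted with a negative correlation within label numbers, were thus not matched by the sums. All 4 falls of colesevelam against vehicle missed the threshold in the sums, with the replicate block, with upper-quartile factors, with the 50 CPM filter and with the authors' size factors, where every call was a rise.

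Past the threshold in every fit chosen in advance were 3 of 7, 4 of 12 and 14 of 24 calls; the 4 were miR-182, miR-183-5p, miR-146a-5p and miR-146b-5p. With the authors' size factors these log2 fold changes reversed. In vehicle against lean miR-140-3p moved to −1.27, miR-378a-3p to −1.64, miR-29a-3p to −2.09, miR-21-5p to −2.11, miR-103-3p to −2.02 and miR-107-3p to −2.24. In colesevelam against lean miR-21-3p moved to −0.92, miR-183-5p to −1.07, miR-182 to −1.38, miR-146b-5p to −1.32, miR-146a-5p to −1.43, miR-99b-5p to −1.59, miR-191a-5p to −1.90, miR-99a-5p to −2.13, miR-23a-3p to −1.96, miR-378a-3p to −2.02, miR-10a-5p to −2.07, miR-23b-3p to −2.01, miR-122-5p to −2.33, miR-29a-3p to −2.48, miR-21-5p to −2.73, miR-103-3p to −2.20 and miR-107-3p to −2.75. The correlation between the comparisons that share vehicle libraries was −0.28, −0.17 with those libraries split, −0.23 with the 50 CPM filter and −0.21 without miR-6215. Summing isomiR rows and other pseudocounts were not run, since the table holds counts and does not split isomiRs. Depth limits rare miRNAs: after thinning 89 could be tested, and 6, 8 and 18 were called.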

Other observations

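The tests of the miR-99 clusters and of the miR-21 arms were chosen only after the result was seen, and so was the naming of untested miRNAs below other than miR-34a-5p and miR-144-3p.

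Without a filter on low counts 12 calls fell on 11 miRNAs that were otherwise not tested. miR-34a-5p, a miRNA repressed by the bile acid receptor FXR, had 24 counts over the lean, 8 over the vehicle and 29 over the colesevelam libraries, which is 12.2, 20 and 72.9 CPM of the summed libraries. Its log2 fold change for colesevelam against lean was 2.28 (edgeR adjusted p = 0.00762), with 0 to 14 counts per colesevelam library, the 14 in colesevelam 3. For colesevelam against vehicle miR-34a-5p was not called. miR-193a-3p had 306, 66 and 13 counts in lean, vehicle and colesevelam libraries and a log2 fold change of −2.10 for colesevelam against vehicle (edgeR adjusted p = 0.0380). miR-200a-3p, of the same family as miR-200b-3p, had 107, 11 and 4 counts, and miR-142-3p, the other arm of the leukocyte miR-142 precursor, 63, 5 and 1, with log2 fold changes of −2.40 and −3.11 for colesevelam against lean (edgeR adjusted p = 0.0142 and 0.0383). The erythroid miR-144-3p had 157, 22 and 15 counts, and was not called.

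A candidate explanation for the rise of miR-99a-5p and miR-99b-5p with colesevelam is that their whole primary transcripts rose, since in GRCr8 their genes neighbour those of let-7c and miR-125b and of let-7e and miR-125a. The mean log2 fold change of the pair was 1.01 and that of the 4 cluster mates 0.14, a difference of 0.87 ± 0.25 (SE, with the miRNAs taken as independent). This argues against an equal rise of these mature miRNAs. It cannot decide for a transcript whose mates also come from elsewhere. The mate let-7c-5p is listed on chromosome 7 as well as on chromosome 11, where miR-99a-5p lies.

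miR-21-3p and miR-21-5p come from one precursor. The log2 ratio of the arms was −9.38 ± 0.72 in lean, −6.72 ± 0.84 in vehicle and −7.41 ± 0.75 in colesevelam libraries (SD, n = 6). It was higher by 2.66 in vehicle and by 1.96 in colesevelam than in lean libraries (exact permutation p = 0.00216 for both, the smallest possible, adjusted p = 0.0216), and each of the 6 libraries of either obese group lay above every lean one. The obese groups differed by −0.69 (exact permutation p = 0.158). The ratio does not depend on the scaling between libraries. It can depend on GC bias, as the GC content is 59.1% for miR-21-3p and 36.4% for miR-21-5p, and no ratio corrected for GC was computed. The mean GC slope, in log2 per 10 points, differed by 0.187 for vehicle against lean and by 0.015 for colesevelam against lean. Between colesevelam and vehicle it differed by −0.173, so part of the −0.69 may come from GC content. A shift between the arms, in processing or in stability, may explain it, as a hypothesis found and tested on the same data.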
